A study of Mus musculus with 24 samples.

How the data were processed

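RNA was measured in B cells sorted from mouse spleen by flow cytometry. Marginal zone (MZ) cells were taken as B220-positive cells bright for CD21 and without CD23, and follicular (FO) cells as B220-positive cells low for CD21 and with CD23. Each kind of cell came from wild-type C57BL/6J mice and from mice in which Irf8 was deleted with a Cre recombinase under CD19 control, per the labels. This gave 4 groups of 6 arrays, 24 arrays in all, and the 6 arrays of a group are biological replicates from individual mice, per the labels. The labels name no Cre in the wild-type mice, so deletion of Irf8 and presence of the Cre are compared together.

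RNA of the sorted cells was treated with DNase and amplified with the Ribo-SPIA method, and the double-stranded cDNA was fragmented and end-labelled with biotin, per the labels' protocols. The array is an Affymetrix whole-transcript mouse gene array, whose probes lie along the length of each gene. The deposited values are log2 probe-set signals, 1 column per array. GCOS 1.4 and RMA are named in the submitters' processing notes, with no role or order given. RMA commonly means background correction, quantile normalization between arrays and summary of the probes of a set. The genome build of the array annotation and the annotation version are not given in the sources used here, so no coordinates are printed. Scale was checked on the values: they ran from 2.06 to 13.67, and the medians of the 24 columns lay between 7.57 and 7.64. No value was missing. RMA gives no detection call, so dim and bright probe sets were tested alike, and precision is limited by the number of arrays.

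Of 35557 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12147 had none. Symbols were updated through Entrez gene identifiers in an NCBI RefSeq table of assembly GRCm38.p6; 21698 of the single-symbol probe sets matched and 0 changed name. That table was used for names and for which genes neighbour each other. A gene with over 1 probe set (999 genes) was represented by the set with the highest mean over the 24 arrays, which left 19938 genes. Irf8 had 1 probe set and Cd19 had 0, whether alone or among several symbols, so no Cd19 value is given.

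The main test was limma (version 3.58.1, R 4.3.3): lmFit with a mean for each of the 4 groups over all 24 arrays, then eBayes with default settings, two-sided. All groups entered 1 fit so that they shared an estimate of the spread. The contrasts were knockout against wild type in MZ cells and in FO cells, MZ against FO in wild type and in knockout, and the interaction (the knockout effect in MZ cells minus that in FO cells). P-values were adjusted over the genes of a contrast by the Benjamini-Hochberg method, with a threshold of 0.05. SE below is the moderated standard error of the fit. On simulated data for the comparison of knockout and wild type in MZ cells, run on 19938 genes with 50 genes changed per size, the test recovered 38% of genes changed by 0.25 on the log2 scale, 86% at 0.5, 100% at 1 and 100% at 2. It called 10 unchanged genes among 172 calls. The simulated values were normal and independent between genes. The real knockout comparisons gave 7 and 6 calls, and with so few the adjusted threshold is stricter. The shares recovered can therefore be too high for the real data.

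Altogether 31 gene lists covering B cell subsets, signalling, transcription factors, housekeeping functions, other blood cells and the neighbours of Irf8 and Cd19 were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists of a contrast. Camera was run again with the correlation between genes estimated from the data, and fry was run as an alternative. A list is called below where the preset test passes, and the adjusted p with the estimated correlation is given beside calls that it loses. Named genes followed a rule: Irf8 and Cd19; for each comparison of groups, up to 10 genes with the largest rise and 10 with the largest fall among genes past the threshold whose 6 values in 1 group all lay above the 6 in the other, without clone names; up to 4 members past the threshold from each list by adjusted p, or its most changed member where none passed; and the 3 genes with the smallest interaction p. The lists, the contrasts, the naming rule and the alternatives below, apart from those named as added, were fixed before the data were examined. Lmo2, Cxcr5, Cr2, BC018473, Hs3st1 and Sema5a fall outside the rule and were chosen after their values were seen, as remaining members of short counts or as a gene of the sort. So do Kynu, St6galnac1, St6galnac2, Gprc5b, Slc1a5, Tsc22d3, Pdcd4, Pik3ip1 and Ddit4, which are named after the comparisons.

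Alternatives were all single-symbol probe sets, a filter on dim genes, quantile normalization, median centring, another variance model, array weights, a minimum fold change, a fit on the 12 arrays compared, each array left out in turn, and fits with the replicate number or the mouse as a block. A term for sex, a fit without the 4 arrays numbered 6, the average of both knockout effects and the lists on the 12 arrays compared were added after the data were seen.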

Results

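Gene expression was profiled in splenic MZ and FO B cells of wild-type mice and of mice with Irf8 deleted in B cells, per the labels, with 6 arrays in each of the 4 groups. MZ B cells sit at the border of the white pulp and respond rapidly to blood-borne antigens. FO B cells recirculate through follicles and enter germinal centres. Irf8 encodes a transcription factor of the interferon regulatory factor family that acts in myeloid and B cell development. Correlation between arrays across genes ranged from 0.975 to 0.989 within groups (median 0.984) and from 0.970 to 0.988 between groups (median 0.979). The first principal component, with 20.7% of the variance, separated MZ from FO arrays. Xist and Y-linked probe sets read as female in wild-type number 1 and in knockout numbers 1 and 3, alike in the MZ and FO arrays of a number, so sex was not balanced between the genotypes.

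The targeted gene was examined first. The Irf8 probe set did not fall in the knockout arrays. In MZ cells its signal was 9.37 ± 0.09 in wild type and 9.73 ± 0.08 in knockout (log2, mean ± SD, n = 6 each), a difference of 0.36 (SE 0.07, limma adjusted p = 0.0744) in which all 6 knockout arrays lay above all 6 wild-type arrays. In FO cells it was 9.76 ± 0.12 and 9.94 ± 0.19, a difference of 0.18 (SE 0.07, adjusted p = 0.711), or 0.11 without knockout number 1. The labels do not give the deleted part of the gene, and which probes of the set lie in it was not examined. How far the probe set can check the deletion or the genotype labels is therefore unknown. The difference in MZ cells passed the threshold in the fit on the 12 MZ arrays (adjusted p = 0.045) and with array weights (0.39, adjusted p = 0.0166).

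The comparison of knockout and wild type asked which genes depend on Irf8 in each cell type. In MZ cells, 5 genes were higher and 2 lower in the knockout. BC018473, a transcript without an assigned function, rose 6.30-fold (log2 change 2.66, SE 0.41, adjusted p = 0.00514). Sesn1, a stress-responsive inhibitor of mTORC1 signalling, rose 1.82-fold (0.87, SE 0.13, adjusted p = 0.00514). Hs3st1, a heparan sulfate sulfotransferase, rose by 0.68, Polr1b, a subunit of RNA polymerase I, by 0.50, and Abhd17b, a depalmitoylating enzyme, by 0.45. Sema5a, a semaphorin, fell by 0.68 (SE 0.12, adjusted p = 0.0218), and Cd1d2, a gene close in sequence to Cd1d1, fell by 0.48 (SE 0.09, adjusted p = 0.0442). The Cd1d2 value is uncertain because probes of near-identical genes can share signal. In FO cells the corresponding changes were 0.57 for Sesn1 (adjusted p = 0.214), 0.32 for Hs3st1 (0.554) and 0.03 for Cd1d2 (0.987).

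The calls in MZ cells were 7 of 19938 genes, with 1104 genes at an unadjusted p under 0.05 where 997 are expected with no effect. Without the 4 arrays numbered 6 the count was 26, of which 6 were among the 7. Leaving out 1 array gave 4 genes without wild-type number 3, 13 without wild-type number 6 and 14 without knockout number 6. Sesn1, BC018473, Polr1b and Hs3st1 passed in each of the 12 fits that left out 1 MZ array, Abhd17b in 11, Sema5a in 6 and Cd1d2 in 5. In the fit on the 12 MZ arrays 6 genes passed, of which Sesn1, BC018473 and Abhd17b were among the 7, whereas Polr1b, Hs3st1, Sema5a and Cd1d2 did not pass.

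In FO cells, 2 genes were higher and 4 lower in the knockout. BC018473 rose 5.08-fold (2.34, SE 0.41, adjusted p = 0.0224) and Zfp1, a zinc finger gene within 100 measured genes of Irf8 on chromosome 8, rose 1.48-fold (0.57, SE 0.09, adjusted p = 0.0187). Kmo, which encodes kynurenine monooxygenase of tryptophan breakdown, fell by 0.56 (SE 0.10), and Lrrk2, a leucine-rich repeat kinase, fell by 0.51 (SE 0.09). Washc4, a subunit of the WASH complex on endosomes, and Itgb7, the integrin beta chain of gut-homing receptors, each fell by 0.36 (SE 0.06). These 4 falls had the same adjusted p of 0.0224. In MZ cells the changes were -0.38 for Kmo (adjusted p = 0.282), -0.32 for Lrrk2 (0.332), 0.27 for Zfp1 (0.621), -0.16 for Washc4 (0.737) and 0.02 for Itgb7 (0.993).

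The calls in FO cells were 6 genes, with 1230 at an unadjusted p under 0.05 where 997 are expected. These counts depended on single arrays: leaving out wild-type number 3 or knockout number 1, 2, 3 or 4 gave 0 calls, wild-type number 2 gave 1, number 6 gave 2 and number 5 gave 3, whereas leaving out knockout number 6 gave 12 and leaving out all arrays numbered 6 gave 15, of which 5 were among the 6. Of the 12 fits that left out 1 FO array, Zfp1 passed in 7, Lrrk2 in 5, Kmo, Washc4 and Itgb7 in 4 each and BC018473 in 2. In the fit on the 12 FO arrays 3 genes passed, of which Zfp1 and Washc4 were among the 6, whereas Kmo, Lrrk2, Itgb7 and BC018473 did not pass.

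**Figure D1:**
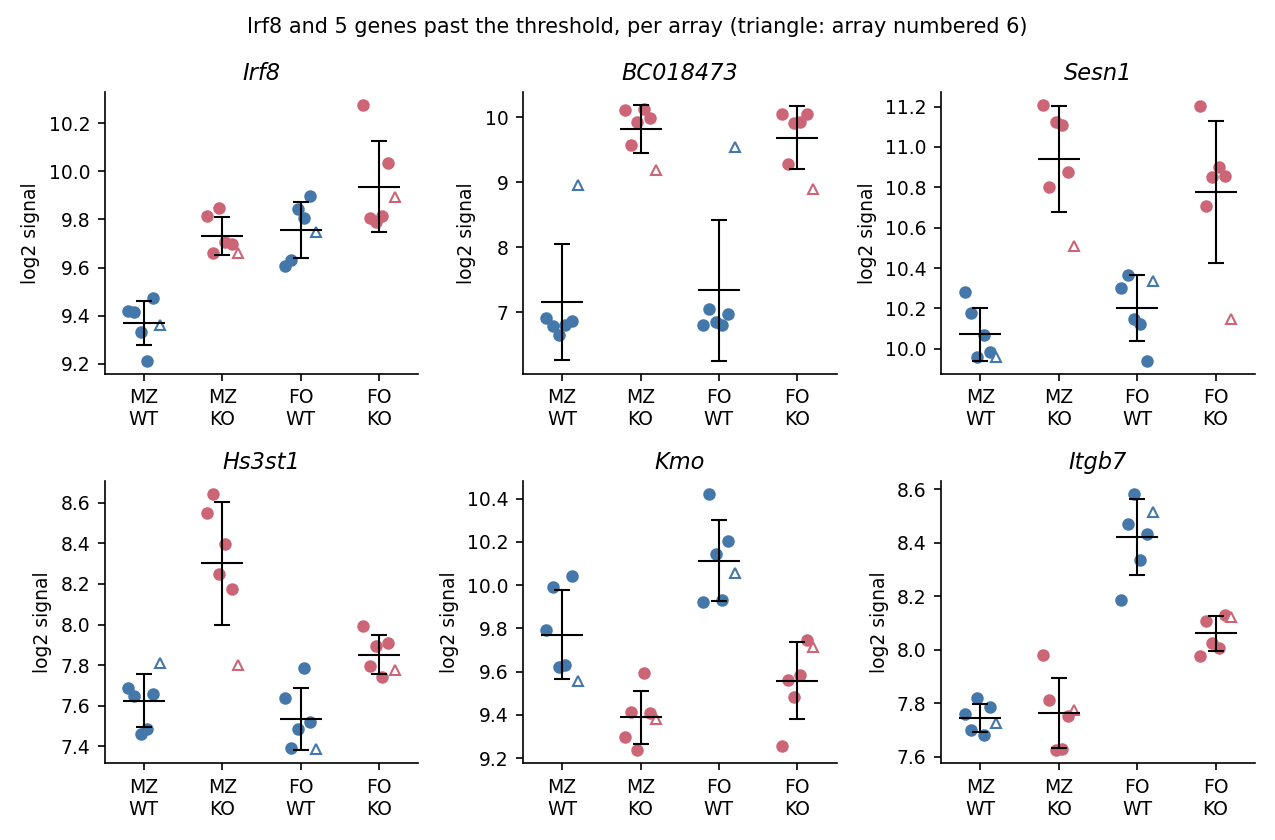
Log2 signal (y axis) of Irf8 and 5 genes past the threshold in at least 1 cell type, for each array of the 4 groups (x axis), with circles for arrays numbered 1 to 5, open triangles for those numbered 6, and bars for the mean ± SD of 6 arrays. Wild-type BC018473 values lie between 6.65 and 7.06 except for the arrays numbered 6, at 8.96 in MZ and 9.55 in FO cells.

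BC018473 was the single gene called in both cell types, with its FO call kept in 2 of 12 fits that left out 1 array, where 0.0005 would be expected to rise in both if the calls were independent. That expectation does not hold if the MZ and FO arrays of a number share a mouse, which their matching sex leaves possible. The overlap was 6 genes without the arrays numbered 6, and 0 with the replicate number as a block, on 12 arrays and at an adjusted p under 0.01. The knockout effects in MZ and FO cells correlated across genes with r = 0.227, and genes are not independent replicates. The BC018473 signal in wild type was 7.16 ± 0.89 in MZ cells and 7.34 ± 1.09 in FO cells (n = 6 each), an SD set by wild-type number 6. No gene passed the interaction test in limma, with 977 genes at an unadjusted p under 0.05 where 997 are expected, and 1 gene passed with the replicate number as a block. The smallest interaction p-values were those of Polr1b (0.50), Ptafr, the receptor for platelet-activating factor (-0.41), and Itgb7 (0.38), each with an adjusted p of 0.77.

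Among the gene lists, follicular B cell genes fell as a group in knockout FO cells. Their mean change was -0.14 over 20 measured members (camera adjusted p = 8.77e-07, and adjusted p = 0.00589 with an estimated correlation). On the 12 FO arrays alone the call held at the preset correlation (adjusted p = 1.03e-06) and was lost with an estimated one (adjusted p = 0.121). Itgb7 was the member past the threshold over all genes, and 1 member rose and 4 fell when p-values were adjusted over the list alone. Bcl6, the repressor that drives the germinal centre program, changed by -0.27 (SE 0.09, adjusted p = 0.601). The per-array mean of the list was 9.41 ± 0.07 in wild-type and 9.26 ± 0.05 in knockout FO cells (n = 6 each), and all 6 knockout means lay below the 6 wild-type means. In MZ cells the list had a mean change of 0.03 (adjusted p = 0.0936), with 0 members past the threshold and 3 higher when adjusted over the list alone, and it passed with a term for sex (0.04, adjusted p = 0.031). Fcer2a, which encodes the CD23 of the sort, had the largest change of its members there (0.48, SE 0.12, adjusted p = 0.306, and 0.00769 over the list alone). The interaction of the list was 0.18 and was called (camera adjusted p = 4.94e-08, and adjusted p = 0.00235 with an estimated correlation). Reassignments of genotype, given further below, did not exclude chance for this difference between MZ and FO cells. MZ B cell genes were not called in either cell type, with mean changes of -0.0027 in MZ (adjusted p = 0.794) and 0.04 in FO cells (adjusted p = 0.769). Of 26 members 0 passed the threshold over all genes, and adjusted over the list alone 1 was lower in MZ cells, and 1 was higher and 1 lower in FO cells.

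Several lists passed the preset test with small mean changes and 0 members past the threshold, and none of these calls held with an estimated correlation. Adjusted over the list alone, at most 2 members of any of them passed. Interferon-stimulated genes had a mean of -0.08 in MZ and -0.07 in FO cells (adjusted p = 0.597 and 0.53 with an estimated correlation), and their most changed members were Ifit3 in MZ cells (0.50, SE 0.45) and Eif2ak2 in FO cells (-0.52, SE 0.23). MHC class I presentation genes had means of -0.09 and -0.10 (adjusted p = 0.478 and 0.347 with an estimated correlation), with Calr at -0.40 in MZ and Psmb8 at -0.24 in FO cells. B cell receptor signalling genes averaged 0.05 in MZ cells (adjusted p = 0.478 with an estimated correlation), with Cd72, an inhibitory coreceptor, at 0.26. Oxidative phosphorylation genes averaged 0.03 in MZ cells (adjusted p = 0.597), MHC class II presentation genes -0.07 in FO cells (adjusted p = 0.457), with H2-Ab1 at -0.29, and cytosolic ribosomal protein genes -0.05 in FO cells (adjusted p = 0.537), with Rplp1 at -0.32, each with an estimated correlation. The mean of the oxidative phosphorylation genes in MZ cells changed sign without the arrays numbered 6. Reported IRF8 targets averaged -0.06 in MZ (adjusted p = 0.237) and -0.04 in FO cells (adjusted p = 0.402), with 0 of 20 members past the threshold in each, also when adjusted over the list alone. Notch pathway, germinal centre, plasma cell, B lineage transcription factor, cell cycle, apoptosis, Toll-like receptor, NF-kB, migration and immediate early genes were not called in either cell type, with adjusted p-values of at least 0.127 in MZ and 0.182 in FO cells. That test reads the list mean, so opposite changes can cancel. In the fry test for changes in either direction, 4 lists passed in MZ and 6 in FO cells, the follicular list among both. The others in MZ cells were migration (adjusted p = 0.000722), NF-kB (0.015) and transcription factor genes (0.0211). In FO cells they were apoptosis (0.000351), plasma cell (0.00134), migration (0.00535), NF-kB (0.00596) and transcription factor genes (0.00674). Cxcr4 of the migration list differed by 0.95 in MZ cells (SE 0.19, adjusted p = 0.0842).

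Markers of T cells, NK cells, macrophages and monocytes, dendritic cells, neutrophils, red cells, platelets, B-1 cells and transitional B cells were not called in either knockout comparison, and none of their members passed the threshold. The most changed of the macrophage list were Mpeg1 in MZ cells (-0.54, SE 0.13, adjusted p = 0.243) and Spic in FO cells (-0.72, SE 0.21, adjusted p = 0.429). Ptpn22, a phosphatase on the B-1 list, differed by 0.75 in MZ (adjusted p = 0.352) and 0.91 in FO cells (adjusted p = 0.214), with knockout FO number 6 apart at 9.45. Genes near Cd19 and genes near Irf8 were not called in either cell type.

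The comparison of MZ with FO cells in wild type described the 2 subsets. MZ cells had 396 genes higher and 533 lower than FO cells, with 79 at least 2-fold apart. Tsga13 was 25.8-fold higher in MZ cells (4.69, SE 0.23, adjusted p = 1.12e-12). S1pr3, a receptor for the lipid that holds MZ cells in place, was 5.61-fold higher (2.49, SE 0.13), and Cd36, a scavenger receptor, was 5.33-fold higher (2.41, SE 0.13). Other large differences were Atxn1 (2.52), Zc3h12c (2.44), the Fc receptor-like gene Fcrl5 (2.03), Myof (2.01), Ceacam2 (1.90), Marcks (1.79) and the chemokine-scavenging receptor Ackr3 (1.75). Genes higher in FO cells included Cd200, an inhibitory ligand (-1.52, SE 0.16), Pde2a (-1.48, SE 0.11), Zfp318, needed for IgD expression (-1.42, SE 0.07), Bcl6 (-1.34, SE 0.09), Ms4a4c (-1.34), Gmfg (-1.34), the small nucleolar RNA Snord35b (-1.85) and the complement regulator Cd55 (-1.33) with its near-identical neighbour Cd55b (-1.37), whose separate values are uncertain. Fcer2a, which encodes the CD23 of the sort, had the largest fall (-2.79, SE 0.12), and Cr2, which encodes CD21, was higher in MZ cells (0.78). Both defined the gate and are no finding. Single wild-type FO arrays lay apart for Atxn1 (6.84 in number 1) and Snord35b (8.90 in number 4). Irf8 itself was lower in MZ than in FO cells in wild type (-0.39, SE 0.07, adjusted p = 0.00107).

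In the list of MZ B cell genes, 17 of 26 members were higher and 1 lower in MZ cells (mean 0.80, camera adjusted p = 1.72e-31). Dusp16, a MAP kinase phosphatase, was among them (1.19), and Lmo2 was the lower one (-0.59). Adjusted over the list alone, 19 were higher and 2 lower. In the list of follicular genes 16 of 20 were lower (mean -0.65, adjusted p = 2.96e-35), among them the chromatin organizer Satb1 (-0.74), and 17 were lower when adjusted over the list alone. Without the sort genes the counts were 16 of 25 higher and 15 of 19 lower.

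Other programs separated the subsets. Germinal centre genes were lower in MZ cells as a group, with 6 lower and 1 higher of 18 (mean -0.25, adjusted p = 2.68e-06), including Bach2, a repressor of plasma cell differentiation (-1.04), and Mef2c (-0.49), while the costimulatory gene Cd86 was higher (0.89). Bcl6 belongs to this list, the follicular list and that of IRF8 targets. Plasma cell genes were higher, with 6 of 25 (mean 0.19, adjusted p = 6.52e-05), and those named here act in protein folding and secretion: Pdia4 (1.30), Mzb1 (0.66) and Edem1 (0.65). Toll-like receptor pathway genes were higher, with 6 of 24 (mean 0.24, adjusted p = 0.00245), including Ly96, the partner of TLR4 in sensing endotoxin (2.10), the nucleic acid sensors Tlr3 (1.19) and Tlr7 (1.15), and Cd180 (0.46). B lineage transcription factors were lower as a group, with 10 lower and 3 higher of 29 (mean -0.13, adjusted p = 3.46e-06), including Foxo1 (-0.29) and Klf2 (-0.39). Adjusted over the list alone, 1 germinal centre gene was higher and 7 lower, 9 plasma cell and 8 Toll-like receptor genes were higher, and 4 transcription factors were higher and 11 lower. These lists held with an estimated correlation, the weakest of them at an adjusted p of 0.0469. On the 12 wild-type arrays alone with an estimated correlation, the calls of plasma cell genes (adjusted p = 0.0948) and B lineage transcription factors (adjusted p = 0.177) were lost.

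Further lists gave calls that an estimated correlation did not keep. Migration and adhesion genes went both ways, with 4 higher and 10 lower of 31 (mean -0.11, adjusted p = 0.0569 with an estimated correlation), such as S1pr1, a receptor for egress from lymphoid tissue (0.55), Itgb7 (-0.67) and the chemokine receptor Cxcr4 (-1.27). Immediate early genes, which respond to handling, included 5 lower of 23 (mean -0.16, adjusted p = 0.0569 with an estimated correlation), among them Ier2 (-0.47). Cytosolic ribosomal protein genes included 6 higher of 61 (mean 0.11, adjusted p = 0.194 with an estimated correlation), such as Rpsa (0.23). MHC class II presentation genes included 2 higher and 2 lower of 18 (mean -0.05, adjusted p = 0.281 with an estimated correlation), with the protease gene Ctsb at 0.57 and the transactivator gene Ciita at -0.26. B-1 cell markers included 2 higher of 15 (mean 0.21, adjusted p = 0.0569 with an estimated correlation), Tbc1d9 (0.87) and Dtx1 (0.72). Dtx1, a NOTCH2 target that also belongs to the MZ and Notch lists, was higher with Asb2 (0.48) and Hes5 (0.16), whereas Lfng was lower (-0.25); the Notch list as a whole was not called (adjusted p = 0.107). Adjusted over the list alone, 5 migration genes were higher and 15 lower, 10 immediate early genes were lower, 18 ribosomal and 4 B-1 genes were higher, and 2 MHC class II genes were higher and 4 lower.

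B cell receptor signalling genes moved both ways, with 5 higher and 4 lower of 30 (adjusted p = 0.113), for example the kinase gene Blk (0.62), Cd81 (0.64) and the BTK inhibitor Sh3bp5 (-0.45). Genes near Cd19 were lower as a group in MZ cells, with 4 of 22 (mean -0.10, adjusted p = 0.0168, and adjusted p = 0.0373 with an estimated correlation), a call lost on the 12 wild-type arrays alone with an estimated correlation (adjusted p = 0.0631). These include Il4ra (-0.75), which also belongs to the follicular list, and Nsmce1 (-0.57). Macrophage markers were not called as a list (adjusted p = 0.196), while Mpeg1 (1.26) and Ms4a7 (1.05) were higher in MZ cells. None of the markers of T cells, NK cells, dendritic cells, neutrophils, red cells or platelets passed the threshold. Interferon-stimulated, MHC class I, IRF8 target, cell cycle, apoptosis, NF-kB, oxidative phosphorylation, transitional B cell and sex-linked genes and genes near Irf8 were not called, with adjusted p-values of at least 0.142. This test reads the list mean, so opposite changes can cancel. Past the threshold, reported IRF8 targets had 4 higher and 3 lower of 20, and transitional B cell markers 1 higher and 3 lower of 15. Of all genes, 4.66% passed.

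**Figure D2:**
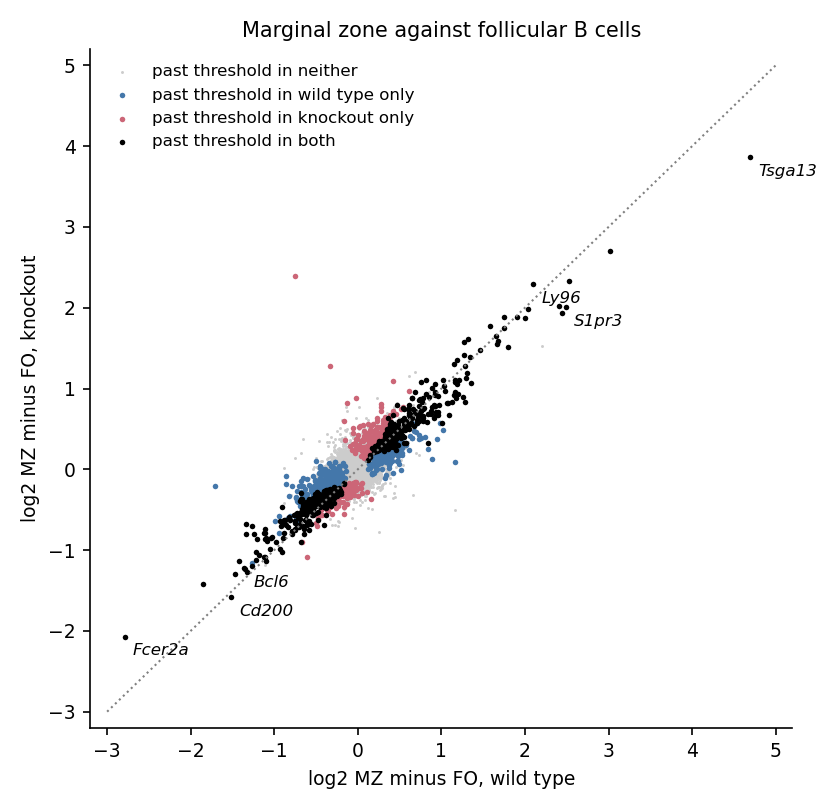
Log2 difference between MZ and FO cells in wild type (x axis) and in knockout (y axis) for 19938 genes, coloured by the threshold of an adjusted p of 0.05. The dotted line marks equal differences, and 469 genes passed in both genotypes.

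The same comparison in knockout mice asked whether the subsets remained distinct in them. MZ cells had 382 genes higher and 328 lower than FO cells, with 58 at least 2-fold apart. The leading genes were Tsga13 (3.86, SE 0.23), Atxn1 (2.34), Ly96 (2.30), Cd36 (2.02), S1pr3 (2.01), Fcrl5 (1.98), Zc3h12c (1.94), Ceacam2 (1.89), Myof (1.87) and Trps1, a GATA-type repressor (1.78). Lower in MZ cells were Cd200 (-1.58), Snord35b (-1.42), Pde2a (-1.30), Cd55 (-1.27), Bcl6 (-1.23), Cd55b (-1.23), the proton channel gene Hvcn1 (-1.19), Vim, which encodes vimentin (-1.14), and Zfp318 (-1.13). The sort genes Fcer2a (-2.07) and Cr2 (0.66) again differed. Irf8 differed by -0.21 (SE 0.07, adjusted p = 0.144).

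Of the genes called in wild type and in knockout, 226 were higher and 243 lower in both, where 7.59 and 8.77 would be shared by independent lists of these sizes. The comparisons share no array. Of 929 genes called in wild type, 903 had the same sign in knockout, and the differences correlated across genes with r = 0.712. The median ratio of the knockout to the wild-type difference was 0.741 for genes called in wild type and 1.04 for those called in knockout, each chosen in 1 genotype and so open to selection.

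In the knockout, 18 of 26 MZ B cell genes were higher and 1, Lmo2 (-0.64), lower (mean 0.76, adjusted p = 1.83e-35). Of the follicular genes 12 of 20 were lower and 1, the follicle-homing receptor gene Cxcr5 (0.44), was higher (mean -0.47, adjusted p = 3.21e-21). Germinal centre genes (4 lower and 1 higher of 18, adjusted p = 9.92e-06) and plasma cell genes (7 higher of 25, adjusted p = 3.47e-07) were again called, with Bach2 at -0.85, Cd86 at 0.77, Pdia4 at 1.13 and Mzb1 at 0.74. Toll-like receptor genes (5 higher of 24, adjusted p = 0.00215) included Tlr7 (1.31) and Tlr3 (1.06). The Notch list was called, with 2 higher and 1 lower of 25 (mean 0.08, adjusted p = 0.013), including Dtx1 (0.70). Genes near Cd19 were called (4 lower of 22, adjusted p = 0.000144), including Il4ra (-0.74). Each of these kept its call with an estimated correlation, while on the 12 knockout arrays alone with an estimated correlation Notch and Toll-like receptor genes did not (adjusted p = 0.0906 for each). Adjusted over the list alone, 18 MZ genes were higher and 1 lower, 1 follicular gene was higher and 14 lower, 1 germinal centre gene was higher and 9 lower, 9 plasma cell and 6 Toll-like receptor genes were higher, and 5 genes near Cd19 were lower.

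Cytosolic ribosomal protein genes were higher in knockout MZ cells, with 25 of 61 past the threshold and 43 when adjusted over the list alone (mean 0.18, adjusted p = 3.12e-33, and adjusted p = 0.0251 with an estimated correlation), such as Rpl37a (0.36) and Rpl36a (0.27). The difference of this list from wild type was 0.07 in the interaction (adjusted p = 8.74e-07, and adjusted p = 0.78 with an estimated correlation). B lineage transcription factors (8 lower and 3 higher of 29, adjusted p = 0.0894 with an estimated correlation) included Id3 (-0.56). Immediate early genes (4 lower of 23, adjusted p = 0.151 with an estimated correlation) included Cd69 (-1.09), B-1 markers had 2 higher of 15 (adjusted p = 0.0682 with an estimated correlation), transitional B cell markers 1 higher and 3 lower of 15 (adjusted p = 0.196 with an estimated correlation), and oxidative phosphorylation genes 0 of 77 (mean 0.05, adjusted p = 0.609 with an estimated correlation). Migration genes were not called (adjusted p = 0.503), with 4 higher and 8 lower of 31, among them S1pr1 (0.56), Ccr7 (-0.42) and Ccr6 (-0.54). B cell receptor signalling genes were not called (adjusted p = 0.892), with Blk at 0.55. Of other cell types, Mpeg1 (0.89) and Ms4a7 (0.97) were higher, and Itgb3, a platelet marker, was lower (-0.31, adjusted p = 0.0411). MHC class I and II, interferon-stimulated, IRF8 target, cell cycle, apoptosis, NF-kB and sex-linked genes, genes near Irf8 and the lists of other blood cells were not called, with adjusted p-values of at least 0.224. Reported IRF8 targets again went both ways, with 3 higher and 3 lower of 20 past the threshold, where 3.56% of all genes passed.

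**Figure D3:**
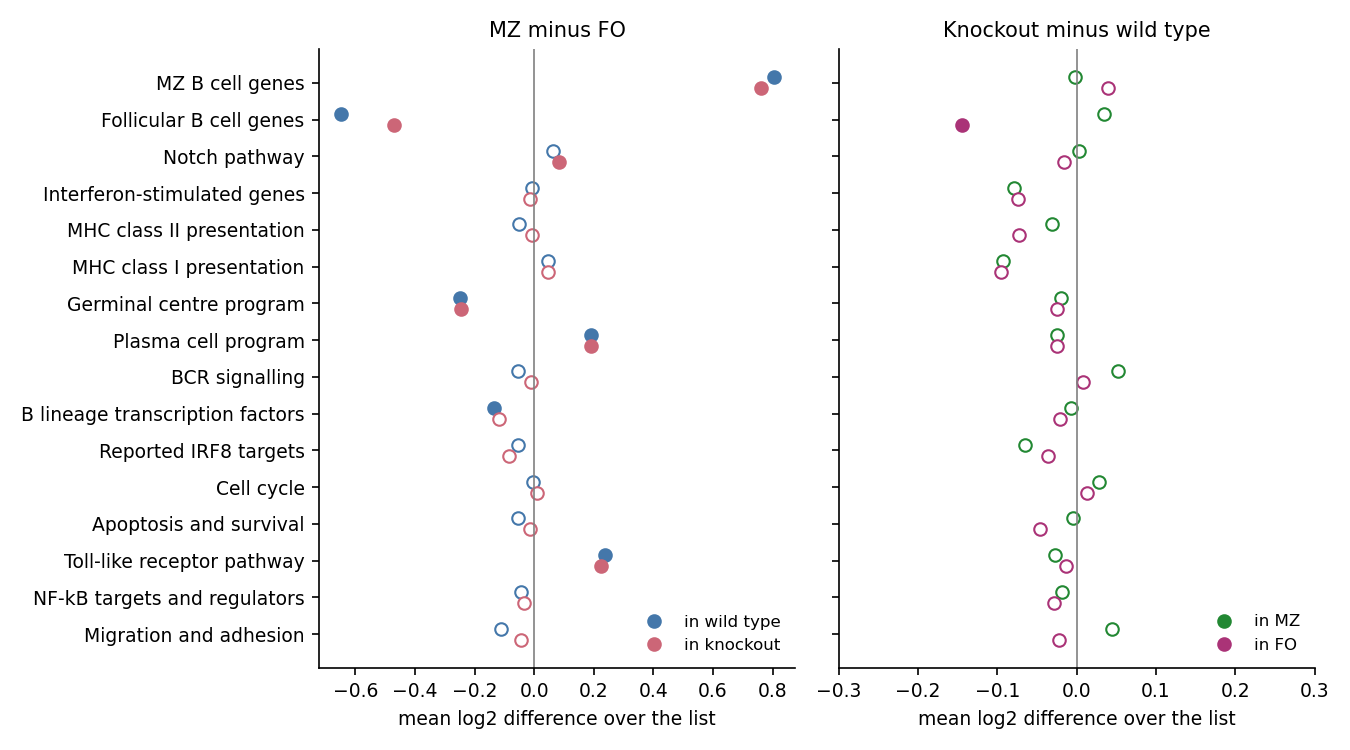
Mean log2 difference over the members of 16 gene lists (x axis), for MZ minus FO in each genotype (left) and knockout minus wild type in each cell type (right, on an expanded scale). Filled points are lists with an adjusted p under 0.05 both at the preset and at the estimated correlation; among knockout comparisons this is the follicular list in FO cells alone, at -0.14, which did not pass with an estimated correlation on 12 arrays.

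**Figure D4:**
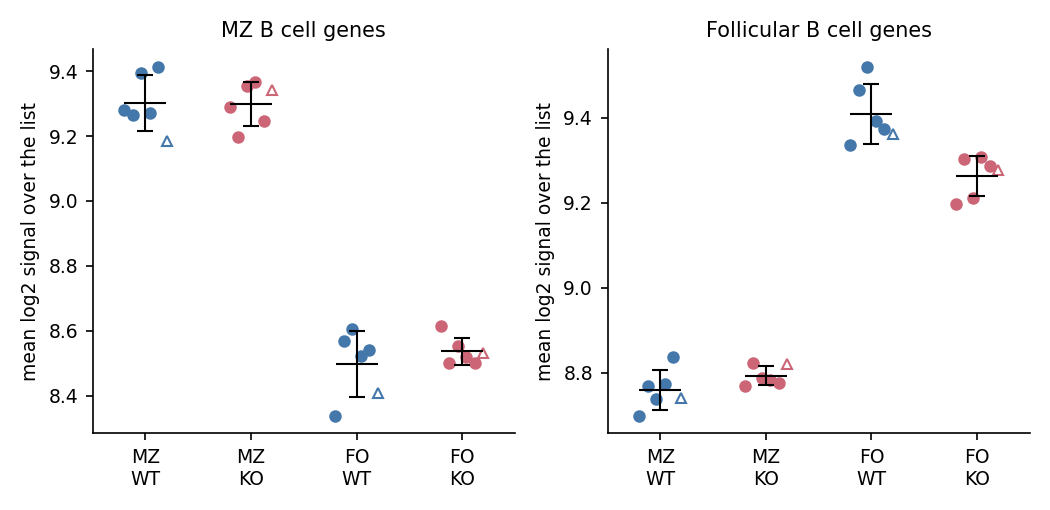
Mean log2 signal over the MZ B cell list (left, 26 genes) and the follicular list (right, 20 genes) for each array of the 4 groups (x axis). Circles are arrays numbered 1 to 5, open triangles those numbered 6, and bars the mean ± SD of 6 arrays; the follicular list lies between 9.34 and 9.52 in wild-type and between 9.20 and 9.31 in knockout FO cells.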

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

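Every test of the arrays numbered 6, the test of wild-type number 6 at BC018473, those of the neighbours of BC018473, of neighbouring pairs and of the genes past the threshold near Irf8 and Cd19, the tests of mixed cells and of sex, and the splits with an estimated correlation or with MZ and FO arrays reassigned independently for the average effect were chosen only after the results were seen.

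Knockout number 6 stood between the genotypes on a scale from the wild-type mean (0) to the knockout mean (1), read over the 92 genes passing in the average knockout effect without the arrays numbered 6 and over the 35 passing with all arrays, a choice that favours the given labels. Its median was 0.38 on the first genes, against 0.77 to 1.22 for knockout numbers 1 to 5 each held out in the same way over 9 to 28 genes, and 0.60 on the second, against 0.99 to 1.43, as a smaller knockout effect in number 6 would give, a hypothesis found and tested on the same data. Exchanged labels with a full knockout effect in number 6 are argued against. Wild-type number 6 had medians of 0.32 and 0.25 and upper quartiles of 0.63 and 0.45, below knockout numbers 1 to 5 on both. Exchanged labels together with a smaller effect in number 6 stay open. On the first genes wild-type and knockout number 6 lay close together (0.32 and 0.38), and the second genes were chosen with the given labels of number 6. On the first genes wild-type number 6 was within the -0.17 to 0.46 of the other wild-type numbers held out in the same way, and on the second above their -0.19 to 0.11. A shared batch stays open, since the deviations of wild-type and knockout number 6 correlated at 0.102, against -0.07 to 0.06 for the other numbers, while incomplete deletion of Irf8 in number 6, a biological explanation, a wrong label of knockout number 6 alone and mixing of the samples were not tested.

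BC018473 was 8.96 in MZ and 9.55 in FO cells of wild-type number 6, against 6.65 to 6.91 and 6.80 to 7.06 in the other wild-type arrays. In assembly GRCm38.p6 it neighbours St6galnac1 and St6galnac2, which also passed in the average knockout effect, and 3 of the 35 genes passing there had another within 5 measured genes, as did 3.33% of 10000 random sets. A variant segment of chromosome that differs between mice is a candidate explanation and stays open: the position of wild-type number 6 at BC018473, 0.790 between the genotypes, restates what prompted it. Among the uncalled neighbours 5.26% had p under 0.01, a share above that of 94.0% of 10000 random windows. Those windows had a median of 2.50%, and at least 1 in 20 reached 7.50%. They kept their genes past the threshold, whereas St6galnac1 and St6galnac2 were left out here, so the comparison is not like for like. DNA of another strain flanking Irf8 and Cd19 stays open too, since 2.25% of the 400 nearest measured genes had p under 0.01, against a random median of 2.00%, and 2 genes passing there, Zfp1 near Irf8 and Gprc5b near Cd19, compare with 0.705 expected and were reached by 16.1% of random pairs of windows. Whether the knockout itself acts on BC018473, Zfp1 and Gprc5b stays open.

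The knockout effect on the follicular list was called as different between MZ and FO cells (0.18), though chance is not excluded for it, as described below. Of technical explanations, MZ cells in the knockout FO sort are argued against as the whole cause of the fall in FO cells. The 29.8% of MZ cells that the list would need predicts a mean of 0.34 for the MZ list, where 0.039 was measured (SE 0.045). A smaller share of MZ cells was not tested. FO cells in the knockout MZ sort, of which 6.59% would give Fcer2a its level there, stay open for the 0.03 in MZ cells and leave the -0.14 in FO cells as it is. Sex is argued against as the whole cause, since the list kept -0.13 in FO cells with a term for sex. The list kept -0.14 without Fcer2a, so this gene does not carry the mean by itself. Leaving it out cannot test whether the sort on its protein affected the other members, which stays open. Loss of Irf8 is the biological explanation given by the design, as a hypothesis, with Cre and other differences between the mice open, and on the 12 FO arrays alone the list was not called with an estimated correlation (adjusted p = 0.121).

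Other splits of the 12 arrays were tried with the fit on those arrays, 100 of 462 splits in each comparison. For knockout against wild type in MZ cells, 1 split gave as many genes, the real one, with 6 genes against at most 1 in the others; in FO cells it was again 1, with 3 against at most 1. For MZ against FO the real split was the 1 that gave as many, with 798 genes against at most 6 in wild type and 639 against at most 3 in knockout. For the average knockout effect, with genotype reassigned independently in MZ and FO cells, at most 5 genes passed against the real 35, again 1 of 100, and splits that kept the MZ and FO arrays of a number together gave at most 2, also 1 of 100. Counts this large were thus rare among the splits drawn, though 1 of 100 is the lowest share that these can give. For knockout against wild type the counts come from the fits on 12 arrays. Of their genes, 3 in MZ and 2 in FO cells were among the main calls, so single genes are not covered. For the interaction, 100 of 100 reassignments of genotype gave as many genes as the real 0, at most 2. Counts of gene lists behaved otherwise. In the knockout comparisons 40 splits in MZ cells (real 4, highest other 13) and 30 in FO cells (real 5, highest other 13) gave as many lists, so chance is not excluded there, whereas 4 did in wild-type MZ against FO (real 12, highest other 12) and 1 in knockout (real 13, highest other 9). With an estimated correlation 100 of 100 splits gave as many lists as the real 0 in the knockout comparisons, with at most 6 in MZ and 2 in FO cells, and 1 of 100, the real one, did for MZ against FO in wild type (real 4, highest other 2) and in knockout (real 7, highest other 2). The shift of the follicular list in FO cells (0.14, highest other 0.12) was matched by 1 of 100 splits, the real one, and its interaction (0.18, highest other 0.16) by 1 of 100 reassignments. Among the lists tested, the follicular list had the smallest camera adjusted p in both comparisons. The splits and reassignments were read for this list alone, not for their own most shifted list. These shares therefore make no allowance for the choice of the list and do not exclude chance.

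Cytosolic ribosomal protein genes also differed in knockout effect between the cell types (0.068), as did oxidative phosphorylation genes (0.075), and neither held with an estimated correlation (adjusted p = 0.78 for each).

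Single arrays far from the other 5 of their group were found in 24 of 356 tests of 89 named genes, where chance gives about 1 in 20, and 10 of the 24 were arrays numbered 6. Besides BC018473, those numbered 6 were Ciita at 9.80 and Dtx1 at 8.71 in wild-type FO cells, Gmfg at 9.09 in wild-type MZ cells, Ly96 at 5.37 and Ptpn22 at 9.45 in knockout FO cells, and Ms4a7 at 7.86, Tsga13 at 9.15 and Vim at 8.53 in knockout MZ cells. Arrays numbered 4 gave Il4ra at 10.04 and Klf2 at 8.86 in knockout FO cells, Polr1b at 7.98, Rplp1 at 11.07, Sema5a at 7.87 and Snord35b at 8.90 in wild-type FO cells, and Ptafr at 8.06 in wild-type MZ cells. Arrays numbered 1 gave Atxn1 at 6.84 and Il9r at 8.91 in wild-type FO cells, and Cd55b at 6.74, Eif2ak2 at 6.20, H2-Ab1 at 10.91 and Ms4a7 at 6.35 in knockout FO cells. Wild-type FO number 2 gave Tlr3 at 7.13.

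Probe sets with no symbol or with several were not used above. Of 13768 such sets, 174 differed between MZ and FO cells in wild type and 187 in knockout, and 0 differed with the knockout in either cell type.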

How the results depend on the processing

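The term for sex, the fits without the arrays numbered 6, the average knockout effect and the lists on 12 arrays were chosen only after the data were seen. In MZ cells the 7 genes became 16 with array weights, 14 with the replicate number as a block, 26 without the arrays numbered 6 and 1 at an absolute log2 change of at least 1. In FO cells the 6 genes became 3 with that block, 3 in the fit on 12 arrays, 15 without the arrays numbered 6 and 1 at the minimum change. The overlap of 1 gene became 0 at an adjusted p under 0.01, 0 with the block, 0 on 12 arrays and 6 without the arrays numbered 6. The average effect rose from 35 to 92 genes without those arrays, 34 of them shared. Leaving out 1 array at a time gave 4 to 14 genes in MZ cells (4 without wild-type number 3, 13 without wild-type number 6, 14 without knockout number 6) and 0 to 12 in FO cells (0 without wild-type number 3 or knockout number 1, 2, 3 or 4, 1 without wild-type number 2, 2 without wild-type number 6, 3 without wild-type number 5, 12 without knockout number 6). It gave 769 to 920 genes for MZ against FO in wild type and 583 to 673 in knockout, 0 to 0 for the interaction, and Irf8 changes of 0.33 to 0.38 in MZ and 0.11 to 0.21 in FO cells. At the minimum change 79 and 58 genes separated MZ from FO. The interaction had 1 gene with the replicate number as a block. Irf8 in MZ cells passed with array weights (0.39) and on 12 arrays (0.36). Oxidative phosphorylation genes in MZ cells went from 0.03 to -0.0032 without the arrays numbered 6. The cause was not tested in any of these cases. A minimum change can only lower a count, while fits with fewer arrays gave lower counts in some cases and higher ones in others.

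Whether the numbers make paired samples was checked on deviations from the group means. Own-number correlations ran from 0.01 to 0.12 between MZ and FO cells in wild type, where 3 of 6 arrays matched their own number best, and from 0.05 to 0.23 in knockout, where 5 of 6 did; the sex read from the arrays was the same in all 12 of these pairs. Between genotypes they ran from -0.11 to 0.13. The labels do not say that a number marks a mouse, so no pairing was assumed. With arrays of a genotype and number taken as 1 mouse and used as a block MZ against FO gave 957 genes in wild type and 776 in knockout. With it as a random block the knockout gave 6 genes in MZ and 6 in FO cells.

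Of the values of named genes under all alternatives, 3318 kept direction and side of the threshold, 169 lost and 16 gained their call, 7 that missed the threshold both ways changed sign, and 0 reversed. Of those of the lists 1352 kept both, 79 lost and 4 gained their call, 47 that missed it both ways changed sign and 1 reversed. Array number limits the precision throughout.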

Other observations

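The average of both knockout effects, its fit with a term for sex and the positions of neighbouring genes were tests chosen only after the results were seen, and the FOXO test was chosen after Foxo1, Sesn1, Tsc22d3, Pdcd4, Pik3ip1 and Ddit4 had been seen but before the mean over the other members was computed.

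Averaging the knockout effect over MZ and FO cells gave 35 genes past the threshold, 20 higher and 15 lower. Besides BC018473 (2.50, SE 0.29), Sesn1 (0.72), Kmo (-0.47) and Lrrk2 (-0.41), these included Kynu, kynureninase, which like Kmo acts in tryptophan breakdown (-1.19, SE 0.19, limma adjusted p = 0.00557). The sialyltransferase genes St6galnac1 (0.85, SE 0.15) and St6galnac2 (0.61, SE 0.10), the orphan receptor gene Gprc5b (0.87, SE 0.15), within 100 measured genes of Cd19, the phosphatase gene Ptpn22 (0.83, SE 0.15) and the chemokine receptor gene Cxcr4 (0.66, SE 0.14) were higher. The receptor gene Il9r (-0.46, SE 0.08), on the list of MZ genes, and the amino acid transporter gene Slc1a5 (-0.40, SE 0.07) were lower. Irf8 was higher (0.27, SE 0.05, adjusted p = 0.0178). With a term for sex 30 genes passed, all among the 35. The SEs given here treat all arrays as independent. With arrays of a genotype and number taken as 1 mouse and used as a random block, 34 genes passed, all among the 35.

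St6galnac1 and St6galnac2 had positions of 0.930 and 0.735 in wild-type number 6 between the wild-type mean (0) and the knockout mean (1), where 34 of the 92 genes passing without the arrays numbered 6 lay above 0.5.

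Foxo1 (0.19), Sesn1, Tsc22d3 (0.34) and Pdcd4 (0.31) were higher in the average knockout effect, and each is a FOXO factor or has been reported as a target of one. A hypothesis is that FOXO targets rise as a group because PI3K signalling is lower in knockout B cells, for example where the Cre disrupts 1 copy of Cd19. Over all 31 measured members of a textbook list the mean was 0.07 (camera p = 0.00382 with an estimated correlation), but this includes the 6 members that prompted the test. Over the other 25 members, the mean was 0.0063, with 13 above 0 (camera p = 0.591 with an estimated correlation). No clear rise was seen over these 25 members. They leave out the members that prompted the test, so their mean cannot decide whether the targets rise as a group. A rise of a few targets may still have any cause.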
